A study of Homo sapiens with 4 samples.

How the data were processed

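Messenger RNA of HepG2 cells, a line grown from a human liver tumour, was measured on 4 Affymetrix arrays, per the labels. The input arrays (n = 2) held poly(A)-selected RNA, and the supernatant arrays (n = 2) held the RNA left after an antibody against N1-methyladenosine (m1A) had pulled methylated transcripts down. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates 1 and 2 came from separate cultures, so p-values measure the spread between these samples, which may be technical.

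The submitters' processing notes name RMA, with no version or setting. The deposited value table holds log2 values of 49395 probe sets without gene names. Its columns had medians of 5.67 and 5.44 in input 1 and input 2 and of 5.94 and 5.45 in supernatant 1 and supernatant 2. The arrays had therefore not been brought to 1 distribution, although quantile normalization is a usual step of RMA. The 102 control probe sets were left out and 49293 were tested. No table pairing these probe sets with genes was used here.

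Gene names came from a second table, called the gene table here. It lists deposited intensities on a linear scale for 5210 genes with a single m1A peak (one-peak genes) and 1224 genes without one (non-m1A genes). Its columns are named supernatant A, input A, supernatant B and input B, per the file headers. No column name gives a cell line or a replicate number, so the letters were not matched to replicates 1 and 2. How the intensities were made is not given in the sources used here. With a tolerance of 0.1% and all 4 assignments of letters to numbers, 0 of the 6434 genes had the 4 values of any probe set in the value table. Intensities reached down to 0.03, far below the lowest value of the other table. Of the 6434 symbols, 5924 were current in the RefSeq gene table of GRCh38.p14, 478 matched exactly 1 older symbol and 32 did not match. Symbols are printed as in the gene table, and no coordinates are given because no genome build was named.

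The gene table also holds the authors' deposited ratio and fraction columns. For each one-peak gene, the deposited corrected ratio was the mean of the 2 supernatant/input ratios divided by a constant. Recomputed from the intensities, it came within 0.006 of the deposited ratio in all 5210 genes. The constant was 1.29, the mean of the authors' deposited ratio over the 1224 non-m1A genes. The deposited methylated fraction was 1 minus the corrected ratio, within 0.001.

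Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, unpaired), on the deposited log2 values and on log2 of the deposited intensities. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing. The test on the gene table was added after the value table proved to hold no names. Gene lists were tested with limma's camera at a preset correlation of 0.01. Of 23 fixed lists, 15 had at least 3 measured genes and were tested, 3 had 1 or 2, and 5 had none. The one-peak genes were tested against the non-m1A genes, which stand for the unlisted genes of the planned test. List membership was tested with Fisher's exact test, two-sided. Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. An exact test of 2 arrays against 2 cannot give a two-sided p below 0.333, and the number of arrays limits the precision.

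On simulated data with 67 genes changed by 0.5 on the log2 scale among 6434, limma recovered 8.96%. It recovered 86.6% of 67 genes changed by 1 and 100% of 66 genes changed by 2, with 4 false calls. For the 49293 probe sets as deposited, the same shares were 0%, 2.99% and 97.0% with 8 false calls, and after quantile normalization 2.99%, 91.0% and 100% with 7 false calls. Camera found 20 of 20 simulated lists of 60 genes shifted by -0.1, at an unadjusted p under 0.05. All changed genes and lists were drawn from above the median level, with noise independent between genes. These shares therefore do not cover dim genes, short lists or lists of correlated genes.

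Named genes followed a rule set before the data were examined. It takes up to 12 passing genes per direction, filled up by the smallest unadjusted p and then said not to pass. It also takes up to 4 members per list by the size of limma's moderated statistic, all measured m1A and m6A enzymes and readers, and the 10 highest and 5 lowest deposited fractions. Other genes are said to have been chosen after their values were seen. Bright genes are those at least as bright, by mean intensity, as the dimmest one-peak gene (36.1). Alternatives covered the replicate block, level filters, a trended prior, recentring, each array left out, other set tests and level matching. Added after seeing the data were quantile normalization and median centring, log2(intensity + 32), a restriction to bright genes and other divisors of the ratio. The lists of liver-line genes, of mesenchymal or squamous line genes and of embryonic kidney line genes were also written then, after the levels of APOE, HOXC6 and COL1A1 had been seen. Values of some measured genes are not reported here.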

Results

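The series asked what fraction of each transcript carries m1A, a methylated adenosine that blocks normal base pairing, by measuring what an m1A antibody leaves behind in HepG2 cells. A transcript that is often methylated should be scarcer in the supernatant than in the input. There were 2 input and 2 supernatant arrays. Gene-level values come from the gene table, in which the median intensity of the one-peak genes was 216 in both inputs and 222 in both supernatants. For the non-m1A genes, medians were 44.5 and 42.8 in inputs A and B and 45.8 and 45.7 in supernatants A and B.

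Liver genes were nearly missing from the gene table. It lists only genes with a single m1A peak or none, so genes missing from it need not be missing from the cells. Of the 27 secreted liver proteins in the fixed list, 1 was measured, the apolipoprotein gene APOE. Its intensity was 31.9 ± 1.27 in the input (SD, n = 2), brighter than only 7.49% of the genes. In a list of liver-line genes written after the data were seen, the apolipoprotein gene APOC1 stood at 8.74 ± 2.88 and the transferrin receptor gene TFR2 at 22.1 ± 3.57 in the input, and the transcription factor gene FOXA1 at 107 ± 30.7 (SD, n = 2). The keratin genes KRT8 and KRT18, shared by many epithelial lines, reached 1798 ± 201 and 4982 ± 1005. Of the genes known from mesenchymal or squamous lines, the intermediate filament gene VIM had an input intensity of 6210 ± 508, the galectin gene LGALS1 of 3957 ± 329, the caveolin gene CAV1 of 862 ± 148 and the homeobox gene HOXC6 of 661 ± 37.5, while TGFBI had 184 ± 44.3, S100A2 50.9 ± 1.21 and IL18 48.2 ± 6.68 (SD, n = 2). Over all 6434 genes, the median liver-line gene had a level percentile of 7.49 (7 measured of 50) and the median mesenchymal or squamous line gene one of 78.3 (12 measured of 24). Without APOE and HOXC6, whose levels were seen before these lists were written, they were 20.03 (6 genes) and 76.4 (11 genes). The gene table names no cell line.

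**Figure D1:**
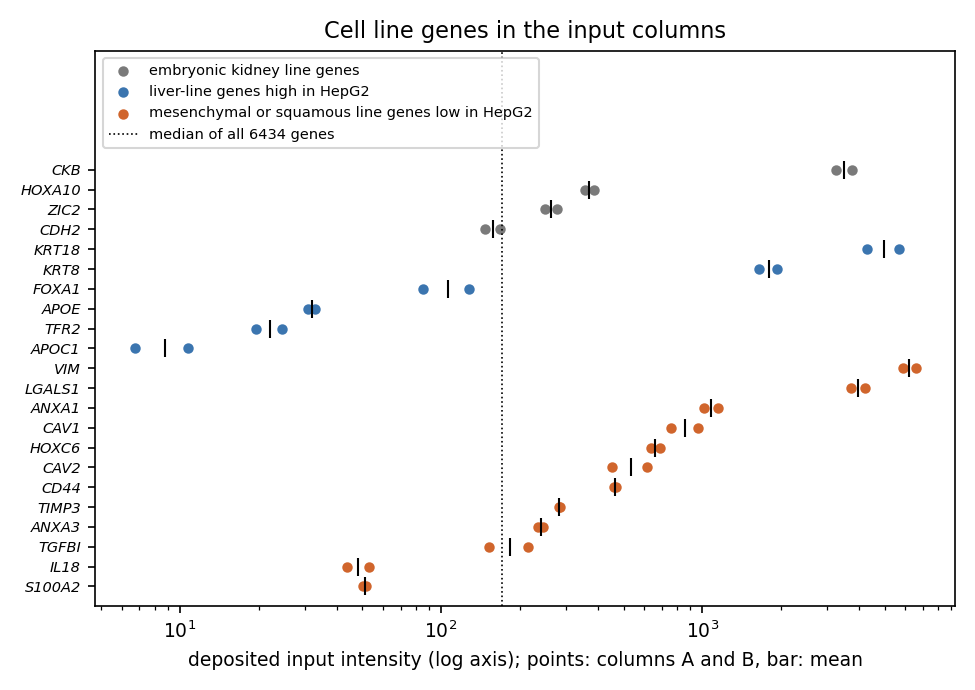
Deposited input intensity (log axis) of 22 of the 23 measured genes from 3 lists of cell line genes, with points for columns A and B, a bar at their mean and a dotted line at the median of all genes. APOC1, TFR2 and APOE lie far left of the line, and VIM, at 6210, lies furthest right.

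The first comparison asked which transcripts the antibody removed. In the gene table, limma called 0 genes lower and 1 gene higher in the supernatant at an adjusted p under 0.05, and 40 lower and 90 higher at an unadjusted p under 0.05. The balance of the unadjusted counts turned with the scaling, to 77 lower and 53 higher after recentring on the non-m1A medians and 74 and 45 after quantile normalization of the columns, and was 128 and 504 without input A. The gene that passed was ZNF134, a zinc finger gene, at intensities of 4.01 ± 0.219 in the supernatant and 0.14 ± 0.0141 in the input (SD, n = 2). Its log2 change was 4.84 ± 0.12 (SE, adjusted p = 0.00327), and with 32 added to every intensity it was 0.16 and no longer passed, nor did it pass with a trended prior. Leaving out 1 column gave 0 to 3 genes lower and 1 to 32 higher, the most without input A. The groups did not overlap in 1478 genes, 23.0%, against 33.3% if all 4 columns were exchangeable. They were not, because same-lettered columns deviated together (correlation of deviations 0.451), which lowers the share. The 23.0% therefore does not show fewer differences than chance.

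Lower values that did not pass were seen in both lettered pairs for several one-peak genes. CCDC71 had an intensity of 88.8 ± 5.05 in the supernatant and 172 ± 3.16 in the input (SD, n = 2). Its log2 change was -0.95 ± 0.09 (SE, limma adjusted p = 0.528). The mitochondrial enzyme gene DLST was at -0.85 ± 0.14 and the kinase genes STK16 and RPS6KA3 at -0.79 ± 0.14 and -0.72 ± 0.09 on the log2 scale. In these 4 genes, and in none of the other one-peak genes, both supernatant values lay at least 0.5 on the log2 scale below both input values, by a margin chosen after the data were seen. Of the 694 bright non-m1A genes, 1 met it, ISM1. When column A was set against column B in the same way, 17 one-peak genes were lower and 11 higher. Same-lettered columns deviated together, so that count is not a measure of independent noise. In the crossed split, supernatant A and input B against supernatant B and input A, 0 one-peak genes were lower and 0 higher. The transcription factor gene PBX2 had a log2 change of -0.55 ± 0.10, the GTPase gene RAC3 of -0.52 ± 0.09, the peptide transporter gene TAP2 of -0.53 ± 0.10 and RAD23B, a DNA repair gene, of -0.50 ± 0.10 (SE). Among non-m1A genes, ISM1 was at -0.98 ± 0.20, and the dim genes PTX4, RCOR2 and TNFRSF10A were at -1.33 ± 0.11, -1.59 ± 0.28 and -0.90 ± 0.14, or -0.09, -0.21 and -0.31 with 32 added. The 11 genes with the next smallest unadjusted p on the higher side, among them EVI2B, PGBD4, ZNF557, ZNF490, GLP2R and NUDT12, were all non-m1A genes dimmer than every one-peak gene, and none passed.

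In the value table, limma called 1 unnamed probe set lower and 2 higher, with 30 lower and 74 higher at an unadjusted p under 0.05. The strongest call was higher by 1.57 ± 0.31 (log2, SE, adjusted p = 0.0177), and the probe set called lower had a log2 change of -1.45 ± 0.31 (adjusted p = 0.0473). Here limma estimated infinite prior degrees of freedom, so every probe set got the same SE of 0.31. It is a spread pooled over all probe sets, not a probe set's own, and the calls follow the size of the change alone. The median change over all probe sets was 0.11 on the log2 scale. The calls were 2 lower and 0 higher after quantile normalization, with 779 and 787 at an unadjusted p under 0.05, and 4 lower and 1 higher after median centring, with 1398 and 608. By the margin of 0.5, chosen after the data were seen, 42 quantile normalized probe sets were lower in both supernatants than in both inputs and 9 higher. Replicate 1 against replicate 2 gave 27 lower and 43 higher, and the crossed split 0 and 0. No probe set passed with a trended prior or without input 2. Calls numbered 7 lower and 2 higher without supernatant 1, with 312 and 34 at an unadjusted p under 0.05, and 1 and 8 without supernatant 2, with 12 and 5592.

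The second comparison asked whether genes with an m1A peak lost more RNA to the antibody than genes without one. They did not pass as a group. The median log2 change was 0.04 in the 5210 one-peak genes and 0.07 in the 1224 non-m1A genes, a difference of -0.03 (a camera p of 0.134). One-peak genes were chosen by the study. The difference was -0.01 in pair A and -0.05 in pair B. Each gene's log2 ratios were also averaged over the pairs and set against non-m1A genes of like level. The difference was then -0.012, 0.814% less RNA (95% interval over resampled genes, -0.0218 to -0.00376). The sign differed between pairs, with 0.00416 in pair A and -0.0339 in pair B. The intervals cover genes, not arrays. One-peak genes also end at a mean ratio of 1.29, the constant of the deposited ratios, with 0 above it. Of the 694 bright non-m1A genes, 14 lay above. Missing high ratios on the one-peak side alone push the difference down, so neither this interval nor a low camera p shows a loss. With each array recentred on the non-m1A medians, camera's p was 0.00213 at the same difference, and the difference was -0.0467 without input A (a camera p of 0.0144) but -0.0013 without input B (a camera p of 0.769).

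**Figure D2:**
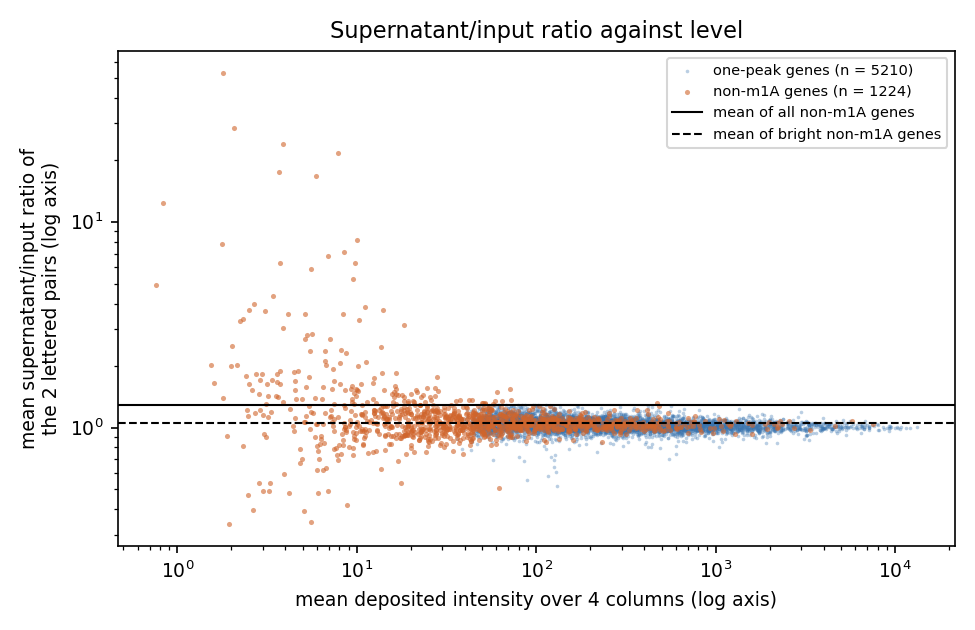
Mean supernatant/input ratio of the 2 lettered pairs against mean intensity over the 4 columns (both axes log) for each one-peak gene (blue) and non-m1A gene (orange). The solid line is the mean ratio of all non-m1A genes, 1.29, and the dashed line that of the bright ones, 1.05, with the highest ratios, up to 52.9, all in dim non-m1A genes.

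The third comparison asked what fraction of each transcript was methylated. In the authors' deposited table the median fraction of the one-peak genes was 0.21, with quartiles of 0.17 and 0.23, and 92.0% of genes lay between 0.10 and 0.30. The highest fraction was 0.60 in CCDC71, followed by 0.57 in DLST, 0.55 in STK16, 0.53 in RPS6KA3 and 0.51 in ATF6B, a stress response transcription factor gene. PBX2 followed at 0.47, TAP2 and RAC3 at 0.46 and RAD23B and the poly-ADP-ribosylating TNKS2 at 0.45. The lowest, RPL4, GSTM4, PCGF1, SCRN3 and MRPL2, were listed at 0, as were 7 genes in all.

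These fractions rest on a divisor of 1.29, the mean ratio of the non-m1A genes, whose median ratio was 1.05. The mean was raised by dim genes. The highest non-m1A ratio, 52.9, belonged to FDXACB1, with intensities of 2.2 and 3.12 in the supernatants and 1.82 and 0.03 in the inputs. ZNF134, LRP4 and RFX7 followed at ratios of 28.7, 22.9 and 21.2. The 12 genes with the highest ratios, all with a mean intensity of at most 10.1, held 54.7% of the summed excess of the ratio over 1, and the 530 non-m1A genes dimmer than every one-peak gene held 90.0%. These genes were chosen after their values were seen. Without a divisor, the median fraction over the one-peak genes was -0.0262 from group means of log2 values, with -0.0239 in pair A and -0.0232 in pair B. From the mean of the 2 ratios, as in the deposited fractions, it was -0.0271 without a divisor and 0.0231 with the mean ratio of the 694 bright non-m1A genes as divisor. CCDC71 then had a fraction of 0.508 (0.534 in pair A and 0.482 in pair B), DLST of 0.471 (0.436 and 0.505) and RPS6KA3 of 0.423 (0.456 and 0.391), while 1813 one-peak genes (34.8%) had a fraction below 0. The deposited fraction and the one recomputed without a divisor had a Spearman's rho of 0.997 across genes (Pearson's r = 0.997). Genes are not independent replicates. Both come from the same intensities and a constant divisor keeps ranks, so a value this high was fixed in advance.

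Most genes did not keep their rank between the pairs. Across the 5210 one-peak genes, log2 ratios of pairs A and B had a Spearman's rho of 0.0605 and a Pearson's r of 0.121 (both permutation p = 0.0005, the smallest that 2000 permutations can give, adjusted p = 0.00125 over 10 correlations). The median gene differed by 0.0592 between pairs on the fraction scale, against deposited quartiles of 0.17 and 0.23. That difference was 0.0839 in the dimmest 1303 genes and 0.0482 in the brightest 1303. In TNKS2 the fraction was 0.382 in pair A and 0.509 in pair B, and in RPL4, a ribosomal protein gene, 0.132 and -0.132. A weak correlation between pairs was also seen over all 1224 non-m1A genes, dim ones included. They had a rho of 0.0793 and an r of 0.152 (permutation test, adjusted p = 0.01 and 0.00125). The 694 bright non-m1A genes had a rho of 0.0272 and an r of 0.0902 (permutation test, adjusted p = 0.511 and 0.03). Whether the correlation is particular to one-peak genes among bright genes is therefore not settled.

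**Figure D3:**
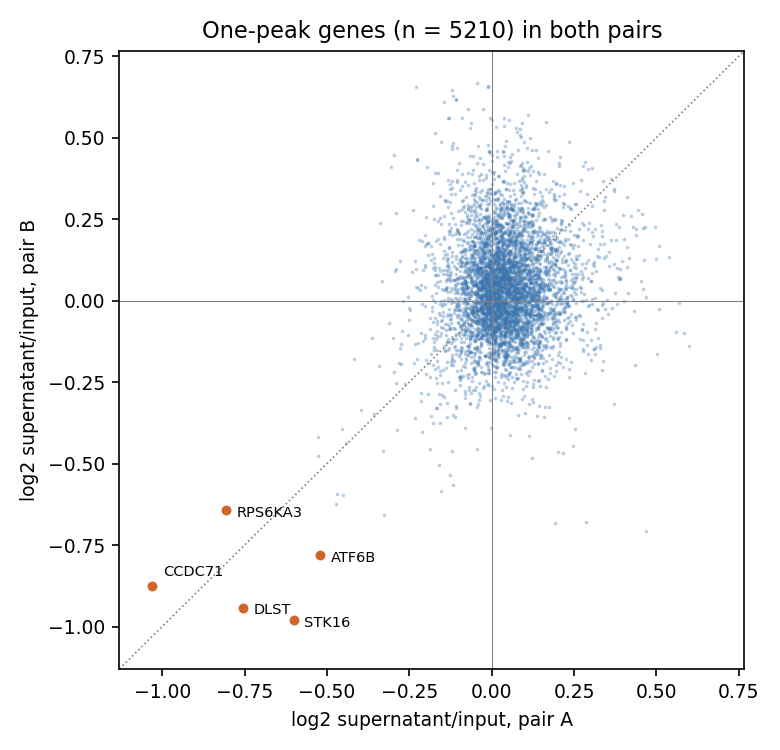
log2 supernatant/input ratio of each one-peak gene in pair B against pair A, with the dotted line at equal values and the 5 highest deposited fractions in orange. Most genes form a round cloud near 0, and CCDC71, DLST, STK16, RPS6KA3 and ATF6B lie apart, low in both pairs.

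The last comparison asked whether gene groups were depleted together. None of the 15 lists tested passed camera. The lowest adjusted p, 0.0553, belonged to 3 long noncoding RNAs. Of these, the nuclear RNA MALAT1 had intensities of 514 ± 43.3 in the supernatant and 689 ± 37.6 in the input (SD, n = 2), a log2 change of -0.42 ± 0.11 (SE) and a deposited fraction of 0.42. EPB41L4A-AS1 and SNHG7 had log2 changes of -0.04 ± 0.09 and 0.00 ± 0.23. Adjusted over the list alone 1 of the 3 passed, MALAT1, and over all genes none. This list had an adjusted p of 0.769 with an estimated correlation, and 0.0148 among genes above the median level, where no list passed with an estimated correlation.

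The 129 zinc finger genes had a median log2 change of 0.07 (adjusted p = 0.0656). Only ZNF134 passed, at the intensities given above, and ZNF557, ZNF490 and ZNF433 had log2 changes of 0.91, 0.71 and 0.75 without passing. All 3 were dim, with intensities of at most 13.1, and with 32 added their changes were 0.09, 0.17 and 0.14. The list's median less that of the other genes was 0.03. It was 0.01 with 32 added, -0.02 among genes above the median level, -0.04 without input B, 0.16 without input A (adjusted p = 3.70e-06) and 0.10 without supernatant B (adjusted p = 0.000165). With an estimated correlation none of these passed, at an adjusted p of 0.769 for all columns and of 0.999 and 0.979 without input A and without supernatant B. Of the 71 nuclear genes of the respiratory chain, which makes mitochondrial ATP, none passed. Their median was 0.00 and their mean -0.01 (adjusted p = 0.0669), with NDUFC2 and NDUFB7 at -0.11 ± 0.09 and -0.14 ± 0.11 and ATP5B at 0.10 ± 0.10. None of the 30 proteasome genes passed, with a median of -0.01 (adjusted p = 0.110), and PSMC5 was at -0.12 ± 0.09, PSMB8 at 0.12 ± 0.11 and PSMA4 at 0.08 ± 0.09. None of the 52 cytosolic ribosomal protein genes passed either, with a median of 0.00 (adjusted p = 0.131), RPS9 at -0.13 ± 0.09 and RPL4 at 0.36 ± 0.22. Recentring on the non-m1A medians ended at 5 lists passing, these 4 and the long noncoding RNAs, with the zinc finger genes up and the others down, and at 0 with an estimated correlation.

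Of the 15 measured enzymes and readers of m1A and m6A, none passed, and the median log2 change was 0.02 (adjusted p = 0.969). The largest was 0.26 ± 0.10 in YTHDC2, an m6A reader and non-m1A gene. The m1A writer subunit TRMT6 had a log2 change of -0.07 ± 0.11, the mitochondrial writers TRMT61B and TRMT10C 0.12 ± 0.13 and 0.05 ± 0.16, HSD17B10 0.01 ± 0.09 and RRP8, which methylates ribosomal RNA, 0.02 ± 0.10. The erasers ALKBH1, ALKBH3, ALKBH5 and FTO were at 0.13 ± 0.14, 0.12 ± 0.09, -0.05 ± 0.11 and 0.02 ± 0.14. METTL14 and WTAP of the m6A writer complex were at -0.13 ± 0.11 and -0.09 ± 0.10, and the readers YTHDC1, YTHDF2 and YTHDF3 at 0.06 ± 0.09, 0.00 ± 0.13 and 0.11 ± 0.12 (all SE).

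In the other 9 tested lists no member passed over all genes and camera's adjusted p was at least 0.553. Among 64 mitochondrial ribosomal protein genes, MRPL2, MRPL38 and MRPL12 had log2 changes of 0.37 ± 0.12, 0.31 ± 0.10 and 0.26 ± 0.09. The immediate early genes JUND, JUNB and KLF2 were at 0.30 ± 0.10, 0.19 ± 0.10 and -0.13 ± 0.10, the mitotic kinase genes PLK1 and BUB1 at 0.29 ± 0.14 and 0.21 ± 0.10, and the chaperone genes HSP90B1 and HSPA5 at 0.19 ± 0.13 and 0.11 ± 0.10. The glycolytic genes PFKP and LDHA were at 0.10 ± 0.09 and 0.03 ± 0.10, the cholesterol synthesis genes HMGCS1 and EBP at 0.21 ± 0.17 and -0.10 ± 0.09, the initiation factor genes EIF4E3 and EIF3G at 0.23 ± 0.17 and -0.12 ± 0.10, EIF2AK3, a kinase of an initiation factor, at 0.19 ± 0.14, the histone genes HIST2H2AC, HIST3H2A and HIST1H2BD at 0.44 ± 0.27, -0.19 ± 0.17 and 0.07 ± 0.12 and the mitochondrial import genes TIMM9 and TIMM8B at 0.14 ± 0.15 and -0.05 ± 0.09. Of the markers of other cell types, CD68 of leukocytes was at 0.07 ± 0.19 and COL1A1 of fibroblasts at 0.35 ± 0.09 (input intensity 51.9 ± 2.89, SD, n = 2). No endothelial or erythroid marker was in the gene table, which does not show that they were absent from the cells.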

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

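Normalization, the block or an estimated correlation combined with another setting, divisors, the brightness limit and the offset of 32 were chosen after seeing the data. The alternatives of the single-gene test in the gene table were not planned either. Replicate numbers are shared between groups but not said to pair them. Deviations of same-numbered arrays correlated at 0.373 in the value table. Those of same-lettered columns correlated at 0.451 in the gene table, and at 0.698 among its bright genes. The authors' deposited ratio was taken within same-lettered columns. With the replicate as a block, limma called 14 probe sets lower and 23 higher (1 and 2 without), 0 and 1 genes as before, and 2 lists passed where 0 had, the respiratory chain genes and the long noncoding RNAs (both adjusted p = 0.0453, and 0.825 with an estimated correlation). Probe sets lower and higher numbered 0 and 1 among those above the median level, 0 and 0 with a trended prior, 3 and 3 at an adjusted p under 0.1, 2 and 0 after quantile normalization and 4 and 1 after median centring. Leaving out each array gave 0 to 7 lower, the 7 without supernatant 1, and 0 to 8 higher, the 8 without supernatant 2. A group left with 1 array was assumed to vary like the other. Quantile normalization with the block gave 42 lower and 8 higher. In the gene table, the block with a trended prior called 33 genes lower and 49 higher. No other alternative that kept all columns called a gene lower, and 0 were higher with a trended prior, above the median level, with 32 added or among bright genes. Leaving out columns gave 0 to 3 lower and 1 to 32 higher, with 3 and 32 without input A and 1 and 11 without input B. Lists passing numbered 5 after recentring, 1 above the median level, 1 with 32 added, 1 among bright genes and 0 to 1 with a column left out, and 0 in each of these with an estimated correlation. One-peak genes are cut at the divisor, which pushes their side of the next comparison down. The one-peak minus non-m1A difference was -0.0281 after recentring (camera p of 0.00213) and -0.0228 above the median level (p of 0.0243), both passing. It was -0.0138 with non-m1A genes matched on level (p of 0.271), -0.00637 with 32 added (p of 0.447), -0.0211 among bright genes (p of 0.140) and had a p of 0.201 with the block, none passing, and ranged from -0.0467 to -0.0013 with a column left out. Fry, which tests the one-peak genes against 0, gave a median of 0.0373 (p of 0.00487). The median fraction was 0.0203 after recentring, -0.0174 above the median level and -0.0249 from linear means. With divisors it was 0.205 (mean ratio of all non-m1A genes), 0.0246 (median ratio), 0.0231 (bright genes) and 0.0938 (without the 12 highest), and it ranged from -0.0275 to -0.0185 with a column left out. The deposited fraction had a rho of 0.553 with pair A alone and of 0.822 with pair B alone. Each pair is part of that fraction, and log2 ratios of one-peak genes spread more in pair B (SD 0.155) than in pair A (SD 0.110). Of the settings of single named genes, of which only ZNF134 passed as deposited, 217 stayed on the same side of the threshold, 7 gained a call and 2, both of ZNF134, lost it. Of the list shifts, none passing as deposited, 18 changed sign, as did the median fraction after recentring. Causes were not tested, except that fewer genes or columns enter some fits. Recentring probe sets on unlisted genes and 1 probe set per symbol were not run because the value table holds no names, nor means over a gene's probe sets because the gene table has 1 value per gene. Low signal limits the dim non-m1A genes, whose ratios spread most.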

Other observations

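The membership tests and all tests below except the count of shared highest genes were chosen after the results were seen. The gene table lists only genes with a single m1A peak or none. Within it, zinc finger genes were listed with a peak less often than other genes. Of the 129 measured, 63 (48.8%) were one-peak genes, against 81.0% of all genes (Fisher's exact test, adjusted p = 1.68e-15 over 15 lists). Among bright genes the shares were 73.3% of 86 and 88.2% (adjusted p = 0.00176). The brightness limit is a floor and did not match the genes on level. Of the 52 cytosolic ribosomal protein genes 96.2% were one-peak genes (adjusted p = 0.0170), but among bright genes the adjusted p was 0.405. No other list passed.

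The genes with the highest fraction in pair A were those of pair B more often than in independent lists. The 100 highest of each pair shared 24 genes, where independent lists share 1.92. Besides the genes named by the deposited fraction, the 24 included MALAT1, the histone methyltransferase gene ASH1L, LMAN1, EXT1, CTSZ and TARS2. TAP2, PBX2 and ATF6B lie in the major histocompatibility complex region, which held 3 of the 24 and 62 of the 5210 one-peak genes, but the region was picked because of these genes, and the median deposited fraction of the 62 was 0.22. One-peak genes end at the divisor, with a highest ratio of 1.29, 21 genes within 0.02 below it and 0 above, whereas 14 of 694 bright non-m1A genes (2.02%) lay above. In the value table, the 5' control probe set of 18S ribosomal RNA was higher in replicate 1 than in replicate 2 by 1.38 in the input and 1.51 in the supernatant (log2). The middle probe set was higher by 1.09 and 1.09, and the 3' one by 0.126 and 0.368. These differences were not corrected for the offset of whole arrays. Array medians were 5.67 and 5.44 in inputs 1 and 2 and 5.94 and 5.45 in supernatants 1 and 2.

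The gene table was deposited with HepG2 samples but shows several dim liver-line genes and several bright mesenchymal or squamous line genes, and the 4 measured embryonic kidney line genes had a median level percentile of 66.8, higher than in 80.6% of random lists. APOE and HOXC6 were seen before the lists were written and were left out of the tests. Failing probe sets averaged into the gene values would dim both lists, and the median percentile of 76.4 for the other 11 genes of the second argues against them as the whole cause. Whether the table may come from cells other than HepG2 cannot be told apart. The other 6 liver-line genes had a median percentile of 20.03, not under the bound of 20 set for the test, and go both ways. The high ones were KRT8 and KRT18, shared by many epithelial lines, at percentiles of 94.3 and 98.9. APOC1, TFR2 and FOXA1 stood at 2.00, 6.22 and 33.8. A HepG2 culture that has lost liver character also stays open and untested.

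The deposited median fraction of 0.21 may come from dividing by a mean that dim non-m1A genes set. With the mean ratio of the bright non-m1A genes as divisor, the median fraction was 0.0231. A loss of one-peak transcripts by the deposited fraction would be -0.34 on the log2 scale relative to non-m1A transcripts of like level. The measured difference of -0.0118, with 0.00416 in pair A and -0.0339 in pair B, argues against such a loss in the supernatant. Its interval reached -0.0218 but covers genes, not arrays. Weak capture by the antibody, which would hide methylated transcripts, stays open.

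The spread of the fraction between genes was weighed against array noise, which if independent and equal in all genes would share 1.92 of the 100 highest genes. Noise is larger in dim genes, and with pair B shuffled within 50 classes of level 2.64 were shared on average and at most 9 in 2000 shuffles. The 24 shared are 12.5 times the 1.92, past the 10 times set before the test, and 9.11 times the 2.64, and with the 6 and 2 shared by opposite ends they argue against independent noise as the whole source at the high end, while the 1 shared by the lowest ends decides nothing because the list is cut there. Whether gene-specific methylation may account for it cannot be told apart, because bright non-m1A genes shared 1 of the 13 highest (0.244 if independent) with a Poisson interval of 0.0253 to 5.57, which leaves room for as strong a sharing without a peak. Spearman's rho between pairs was higher by 0.0333 in one-peak than in bright non-m1A genes (95% interval, -0.0488 to 0.124). That interval lies across both bounds of the test, 0.05 and 0.1. The one-peak rho was higher by 0.0605 (-0.0281 to 0.148) than in the 680 bright non-m1A genes with a mean ratio below the divisor. The order turned with the dim genes included, at a rho of 0.0793 in all 1224 non-m1A genes and 0.0605 in one-peak genes. In the brightest 1303 one-peak genes rho was 0.0466.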
